A study of Bos taurus with 14 samples.

How the data were processed

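Gene expression was measured on 14 microarrays of 1 custom Agilent bovine design, each hybridised with Cy3-labelled RNA from 1 sample of Bos taurus cells. The samples were bovine endometrial stromal cells (BES) and granulocytes, incubated for 2 h with phosphate-buffered saline (PBS) or with interferon tau (IFNT), the type I interferon that the ruminant conceptus secretes in early pregnancy. The labels give the IFNT dose as 1 mg/mL, which is high for an interferon and may be an error of unit, and describe RNA extraction (with TRIzol) for granulocytes alone. There were 3 BES samples with PBS, 3 BES samples with IFNT, 4 granulocyte samples with PBS and 4 granulocyte samples with IFNT. The labels do not say whether replicates came from separate animals or cultures, so every error and p-value measures the spread between these samples and no more.

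The deposited scanner files hold fluorescence intensity for each spot, made with Agilent Feature Extraction 9.5. Their processed signal is an intensity that the authors' scanner software had already corrected for background and spatial trends, with substitute values for spots at background. The authors' value table holds log2 values, and each of its columns was the log2 processed signal of that array minus 1 constant, with no centring of probes between arrays. Each array carried 15208 non-control probes and 536 control spots. All BES arrays lay on 1 slide and all granulocyte arrays on another, so slide and cell type cannot be told apart wherever levels in the cell types are compared. Within the granulocyte slide, the PBS samples filled array row 1 and the IFNT samples array row 2. On the BES slide, PBS samples 1 and 2 lay in array row 1, and PBS sample 3 and all IFNT samples in array row 2.

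Processed signals were taken to log2 and the 75th percentile of each array's non-control probes was subtracted. Spots that the scanner software marked as non-uniform or as population outliers were left out. A probe was tested when the software called it well above background on at least 3 arrays (BES) or 4 arrays (granulocytes), the size of the smaller group compared. For the contrast of the IFNT responses, a probe passed if it met the condition in either cell type. The array number per group limits the precision of every value.

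Groups were compared with limma 3.58.1 in R 4.3.3 (linear fit and moderated test, two-sided), and p-values were adjusted by the Benjamini-Hochberg method over the probes tested, with a threshold of 0.05. IFNT was compared with PBS within each cell type in a separate fit. The difference between the IFNT responses of the cell types, and the difference between granulocytes and BES under PBS, were also tested. For gene counts and gene lists, each gene was represented by its probe with the highest mean level among those tested. Each of 23 gene lists was tested with camera in limma, at a preset correlation of 0.01 between genes and again with the correlation estimated from the data, with p-values adjusted over the lists that had at least 3 measured genes. List members past the threshold were counted after adjustment over all probes and after adjustment over the list alone. Every such count covers only the members that had a named probe and were tested, not the whole list. Overlaps between cell types were tested with Fisher's exact test, two-sided, with 4 overlaps adjusted together.

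The groups, comparisons, tests, gene lists, alternatives and the rule for naming genes were chosen before the data were examined. The rule named, in each cell type, the 12 largest rises and the 8 largest falls among genes past the threshold in which every IFNT array lay on the same side of every PBS array. It also named ISG15, MX1, MX2 and the OAS1 genes whatever their test gave, up to 4 members per list with the smallest unadjusted p, the 8 largest differences between the responses in each direction, and up to 4 members of each cell identity list with the highest mean level. Gene names came from the files' accessions, gene numbers and symbols, looked up in the bovine RefSeq gene table of the ARS-UCD2.0 assembly. Of the probes, 7158 received a symbol (6829 distinct symbols) and 8050 received none. For 992 probes the name rests on a description in the file as similar to a gene, which applies to GBP4, KIF5C, NCOA7, MEFV, IFIT5 and TMPRSS2 among the genes named. Of the genes that the rule selected, 3 are not reported here, though the counts of probes, of list members and of values under the alternatives include them. The files give no genome build and no position is stated here.

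Where a group had no array well above background, the fold was also computed against the lowest signal that each array called well above background, and is given as a lower bound. The fitted log2 change of such a gene depends on the substitute values at background. For the difference between the responses, bounds were computed in the same way, after the data had been seen, and no size or direction is stated where they leave it open. A group counted as measured when any of its arrays was well above background and not all were saturated. A measured group can therefore still hold substitute values.

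The same steps were tested on simulated data with the spread of each comparison, in which 200 probes were changed. In the BES comparison (11309 probes), 77.6% of the probes changed by 0.5 on the log2 scale were found, 94.0% of those changed by 1 and 98.5% of those changed by 2, with 12 false calls. In the granulocyte comparison (10379 probes) the shares were 65.7%, 95.5% and 100%, with 8 false calls. In the contrast of responses (12046 probes) they were 46.3%, 74.6% and 98.5%, with 12 false calls. In the comparison under PBS (11805 probes) they were 50.8%, 67.2% and 95.5%, with 12 false calls. In the order given, false calls were 6.25%, 4.4%, 7.6% and 7.8% of all calls. The noise was drawn independently for each probe, without an effect of array row, and fewer probes changed than passed in the real data. The shares hold for that setting only.

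The alternatives were scaling by each array's median, quantile normalization, normexp background correction with an offset of 50, the authors' value table, no filter on dim probes, a filter on every array, marked spots kept, all 14 arrays in 1 fit, a variance prior with an intensity trend and robust estimation, a block for the replicate number, array row as a covariate, a minimum change of 2-fold, and leaving out each sample in turn. No sample was left out of the results reported. Control spots were not used as a measurement.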

Results

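The series compared the early transcriptional response to IFNT, the pregnancy recognition signal of ruminants, in a resident cell of the uterus and in a circulating leukocyte. The share of probes well above background was 71.6% to 76.1% on the 6 BES arrays and 66.4% to 70.9% on the 8 granulocyte arrays. The 75th percentile of the signal was an intensity of 2564 to 3173 on BES arrays and of 1009 to 1491 on granulocyte arrays. Arrays of 1 group correlated with each other at 0.990 to 0.996 (Pearson's r across probes), and arrays of different cell types at 0.732 to 0.748. These correlations run across probes, which are not independent replicates.

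In BES, 2 h of IFNT raised the classical interferon-stimulated genes by large factors. ISG15, a ubiquitin-like protein that is conjugated to other proteins, rose 342-fold (log2 8.42 ± 0.10, SE, n = 3 against 3). MX1, an antiviral GTPase, rose 117-fold (6.87 ± 0.08), and RSAD2, the antiviral protein viperin, rose 68.4-fold (6.10 ± 0.17). OAS1X, a sensor of double-stranded RNA, rose from background on all PBS arrays to at least 113-fold higher (fitted log2 9.12 ± 0.20). All of them were higher in 3 of 3 IFNT samples than in every PBS sample.

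The other largest rises in BES were in RTP4 (log2 5.64 ± 0.08), XAF1 (5.14 ± 0.15), IFIT3 (5.02 ± 0.10), the deubiquitinase USP18 that removes ISG15 from proteins (4.23 ± 0.09) and the RNA sensor RIGI (3.91 ± 0.06). GBP4, GBP5 and KIF5C were at background under PBS and rose to at least 27.3-fold, 6.06-fold and 4.54-fold higher. GBP4 and GBP5 are guanylate-binding proteins, and KIF5C is a kinesin motor. Adjusted p over these 12 rises ranged from 4.5e-07 to 2.3e-04 (limma). Falls were small. Among the 8 largest were ARFGAP1 (−0.89 ± 0.16, adjusted p 0.0375), GFOD2 (−0.76 ± 0.11), MOGS (−0.75 ± 0.12), PDE2A (−0.74 ± 0.12), TCN2 (−0.72 ± 0.11), GADD45G (−0.68 ± 0.10) and GPI (−0.67 ± 0.11). Each of these 7 lost its call without at least 1 of the samples.

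Of the 22 measured interferon-stimulated genes in BES, 21 rose and none fell, with a median log2 change of 3.76 (22 adjusted over the list alone). The full list has 57 members, of which 24 had a named probe on the array, so much of it was not seen. The list rose against all other genes (camera adjusted p 4.4e-50; adjusted p = 0.0236 with an estimated correlation). MX2 was the member not past the threshold (0.65 ± 0.24, adjusted p 0.168). Of 9 genes of interferon receptor and STAT signalling, 2 rose (4 rose and 1 fell adjusted over the list alone), IRF9 (2.89 ± 0.05) among them. That list's camera adjusted p was 3.9e-03, and adjusted p = 0.167 with an estimated correlation. Of 12 interferon regulatory factors and virus sensors, IRF1 (1.38 ± 0.07), TLR3 (0.56 ± 0.06) and IRF3 (0.61 ± 0.11) rose (3 rose and 1 fell adjusted over the list alone). Of 9 feedback inhibitors, USP18 and DUSP6 (0.45 ± 0.06) rose (3 rose and 1 fell adjusted over the list alone).

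Of 13 genes of MHC class I presentation in BES, B2M (0.53 ± 0.05) and the proteasome activator PSME1 (0.25 ± 0.04) rose (8 rose adjusted over the list alone; camera adjusted p 1.4e-05; adjusted p = 0.167 with an estimated correlation). Of 4 measured genes of MHC class II presentation, BOLA-DMB rose (0.36 ± 0.05). Of 14 chemokines, CCL2 (0.56 ± 0.06) and CXCL10 (0.64 ± 0.12) rose (2 rose and 4 fell adjusted over the list alone), and of 13 inflammatory cytokines and receptors, CSF1 (0.54 ± 0.10) and TNFSF13B, the B cell survival factor BAFF, rose, the latter from background to at least 2.62-fold higher (4 rose and 2 fell adjusted over the list alone). Of 13 immediate-early genes, ATF3 (1.49 ± 0.10), ZFP36 (1.13 ± 0.06) and FOS (0.54 ± 0.08) rose (5 rose and 3 fell adjusted over the list alone). Of 15 genes of apoptosis and survival, CASP8 (1.35 ± 0.15), CASP4 (0.96 ± 0.06), FAS (0.33 ± 0.04) and BIRC3 (0.28 ± 0.04) rose.

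Of 23 stromal and extracellular matrix genes in BES, COL4A1 (−0.30 ± 0.04) and THY1 (−0.36 ± 0.06) fell (1 rose and 2 fell adjusted over the list alone; 1 and 1 with quantile normalization or normexp background correction). Of 25 genes of endometrial prostaglandin and steroid response, none passed the threshold in limma and 7 had an unadjusted p under 0.05. DNAJA1 (0.29 ± 0.04) of 19 stress genes and MUC1 (0.33 ± 0.06) of 12 epithelial markers rose (1 rise in each adjusted over the list alone, and 1 epithelial fall). No gene of the lists for neutrophil granules (9 measured), granulocyte receptors (12), T and NK cells (7), B cells (3), monocytes (9), eosinophils (1), platelets (5), endothelium and smooth muscle (7) or reference genes (12) passed the threshold. Their counts at an unadjusted p under 0.05 were 2, 2, 0, 1, 2, 0, 1, 3 and 1; adjusted over the list alone, 1 granulocyte receptor and 1 B cell marker fell, and 1 endothelial or smooth muscle marker rose and 2 fell.

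In all, 414 of 11309 probes tested in BES passed the threshold (259 up and 155 down; 2874 at an unadjusted p under 0.05). Of these probes, 85 rose and 2 fell at least 2-fold. Among genes with a symbol, each counted by 1 probe, 194 of 5395 passed. Probes without a symbol are left out of that gene count. In 3793 probes (33.5%; chance gives 10%) the IFNT and PBS arrays did not overlap, the 414 among them. With array row as a covariate 149 probes passed. That fit sets the IFNT samples against PBS sample 3 alone, the only PBS sample in array row 2. Its calls therefore do not show the full comparison freed of a row effect. Without IFNT samples 1, 2 or 3, or PBS samples 1 or 2, 183, 194, 200, 215 and 206 passed. Of the genes named, TNFSF13B lost its call without IFNT sample 1, and PSME1, BIRC3, THY1, COL4A1, MUC1, CSF1, CXCL10, DNAJA1, FAS, FOS, DUSP6, BOLA-DMB and IRF3 lost theirs without at least 1 of the samples, while MX2 passed without PBS sample 1. TLR3 and CCL2 lost their calls with array row as a covariate. The split into rises and falls depended on the processing. The 259 rises and 155 falls became 129 and 20 with array row as a covariate, 163 and 26 with no filter on dim probes, 294 and 322 with normexp background correction, and 432 and 579 with the intensity trend and robust prior. Falls numbered 265 with PBS sample 3 left out, when array row and treatment coincided, and 29 to 41 with any other 1 sample left out.

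**Figure D1:**
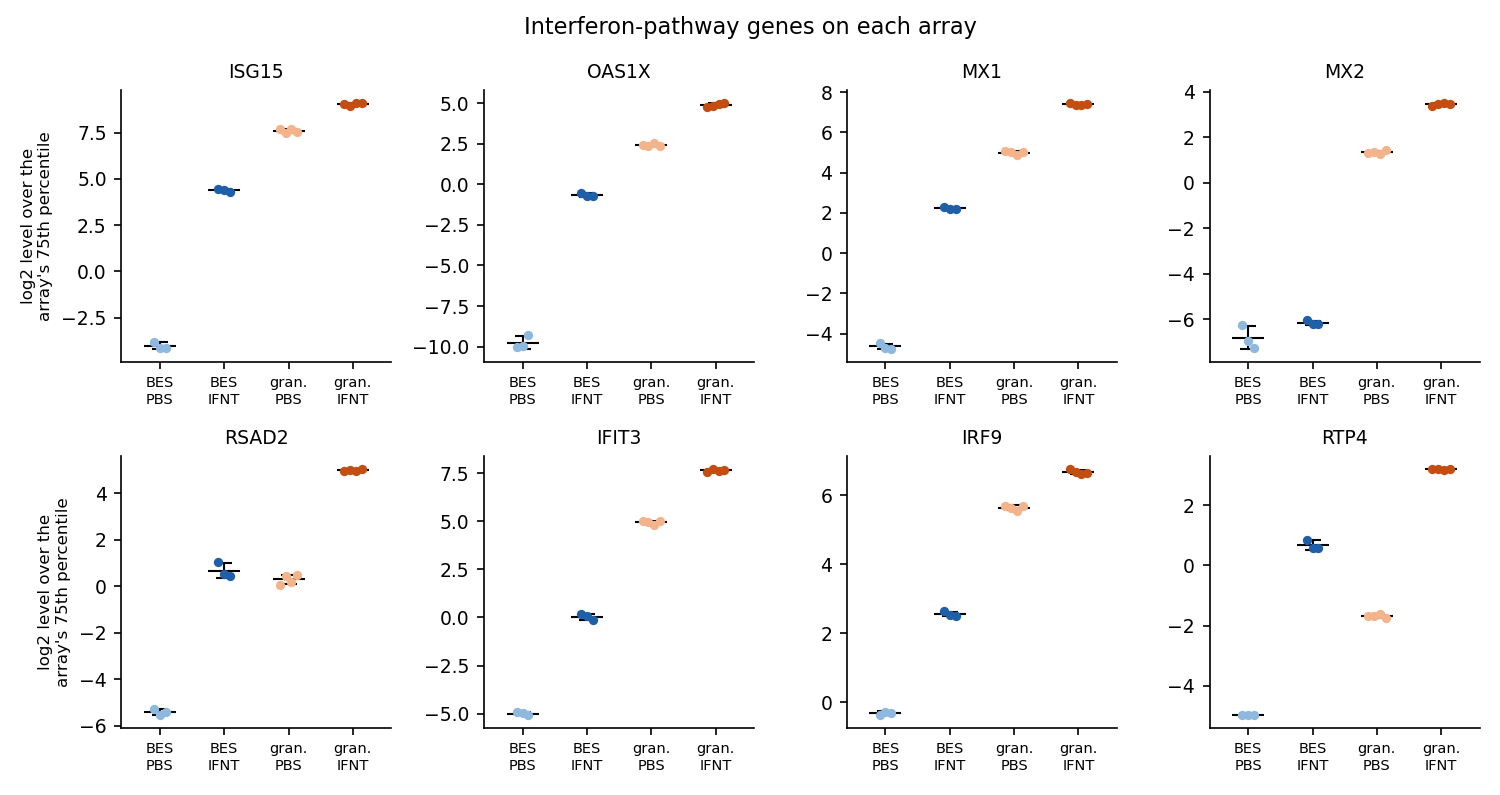
Level of 8 interferon-pathway genes on each array, as log2 over the 75th percentile of that array. Points are samples (3 per BES group, 4 per granulocyte group), and bars are the mean and SD. In BES, ISG15 rose by 8.42 and MX1 by 6.87; in granulocytes the same genes started higher and rose by 1.45 and 2.41, ISG15 with saturated spots on all 4 IFNT arrays.

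In granulocytes, the chemokines CCL8 and CXCL10 were among the 12 largest rises, and the chemokine CCL20 and the chemokine receptor CXCR4 among the 8 largest falls. CCL8, which attracts monocytes and T cells, was at background under PBS and rose to at least 664-fold higher (fitted log2 10.94 ± 0.26, SE, n = 4 against 4). CXCL10, a chemokine for T and NK cells, rose 79.6-fold (6.31 ± 0.05). Adrenomedullin (ADM), a vasodilator peptide, rose 20.5-fold (4.36 ± 0.06), and RTP4 rose 29.2-fold (4.87 ± 0.04). CCL20 fell by 2.93 on the log2 scale (SE 0.17; no IFNT array was well above background, so the fall is at least 1.55-fold), and the chemokine receptor CXCR4 fell by 2.02 (SE 0.10).

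The other largest rises in granulocytes were in GBP5 (4.71 ± 0.09), RSAD2 (4.70 ± 0.10), USP18 (3.98 ± 0.09), GBP4 (3.70 ± 0.07), NCOA7 (3.68 ± 0.04) and DECR2 (4.99 ± 0.06), and in BCL2L14 and SORD, which rose from background to at least 7.06-fold and 3.81-fold higher. Adjusted p over the 12 largest rises ranged from 3.8e-11 to 3.6e-08 (limma). Among the 8 largest falls were 4 beta-defensins, antimicrobial peptides: BNBD-9-LIKE (−2.50 ± 0.09), DEFB13 (−2.32 ± 0.08), tracheal antimicrobial peptide TAP (−2.28 ± 0.10) and lingual antimicrobial peptide LAP (−1.95 ± 0.16). No pair of the beta-defensin probes shared more than 31 aligned bases. MEFV, the gene of pyrin, fell by 1.76 (SE 0.04) and the collagen-processing protein PCOLCE by 1.75 (SE 0.07). Every IFNT array lay above, or below, every PBS array in each of these 20 genes.

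Of 24 measured interferon-stimulated genes in granulocytes, 23 rose and none fell, with a median log2 change of 2.40 (23 adjusted over the list alone; camera adjusted p 5.9e-22; adjusted p = 0.0105 with an estimated correlation). MX1 rose by 2.41 ± 0.06, MX2 by 2.12 ± 0.05, OAS1X by 2.47 ± 0.07, OAS1Z by 1.82 ± 0.12 and IFIT5 by 2.64 ± 0.05. ISG15 rose by 1.45 ± 0.07, but its spots were saturated on all 4 IFNT arrays, so that change is a lower bound. Of 10 genes of interferon receptor and STAT signalling, 3 rose and 4 fell: IRF9 (1.03 ± 0.05) was among the rises, while the receptor chains IFNGR1 (−0.50 ± 0.05) and IFNAR2 (−0.43 ± 0.05) fell. Of 14 interferon regulatory factors and virus sensors, 8 rose and 1 fell, IRF3 (2.56 ± 0.09), IRF1 (1.90 ± 0.12) and TLR4 (1.85 ± 0.05) among the rises (camera adjusted p 7.1e-03; adjusted p = 0.388 with an estimated correlation). Of 9 feedback inhibitors, 4 rose and 3 fell (4 and 4 adjusted over the list alone), with rises in the cytokine signalling inhibitors SOCS2 (1.32 ± 0.08) and CISH (1.28 ± 0.09) and a fall in DUSP6 (−0.92 ± 0.06).

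Inflammatory mediators moved both ways in granulocytes. Of 16 chemokines, 5 rose and 9 fell; the neutrophil attractant GRO1 (−1.41 ± 0.06) and the eosinophil attractant CCL24 (−1.62 ± 0.07) were among the falls. The median change of the chemokine list was −0.22 while its mean was 0.62, and its test did not pass (camera adjusted p 0.441, direction down). Of 20 inflammatory cytokines and receptors, 8 rose and 6 fell (8 and 7 adjusted over the list alone): the macrophage growth factor CSF1 rose (3.03 ± 0.22), TNFSF13B rose (2.91 ± 0.07), IFNB1 rose from background to at least 2.19-fold higher and IL10 fell (−1.16 ± 0.06). Of 12 immediate-early genes, 4 rose and 4 fell, IER2 (0.74 ± 0.06) and ATF3 (0.47 ± 0.05) among the rises. Of 17 genes of apoptosis and survival, 7 rose and 4 fell, with rises in the inflammatory caspases CASP1 (1.02 ± 0.05) and CASP4 (0.77 ± 0.06) and a fall in BIRC3 (−0.38 ± 0.05).

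More presentation genes rose than fell in granulocytes. Of 14 genes of MHC class I presentation, 8 rose and 1 fell, PSME2 (1.05 ± 0.06), PSMB9 (0.86 ± 0.05) and PSME1 (0.71 ± 0.04) among the rises (camera adjusted p 1.1e-03; adjusted p = 0.0693 with an estimated correlation). Of 8 genes of MHC class II presentation, 4 rose and none fell, CTSS (0.39 ± 0.06) and BOLA-DMB (0.39 ± 0.06) among them (camera adjusted p 0.123).

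Genes of granulocyte function also went both ways. Of 15 neutrophil granule and calgranulin genes, 5 rose and 1 fell: the cathelicidins CATHL6 (1.54 ± 0.05) and CATHL2 (1.33 ± 0.09) and lactoferrin (LTF, 1.00 ± 0.06) were among the rises, and the gelatinase MMP9 fell (−0.56 ± 0.05). Of 21 granulocyte receptors and adhesion genes, 5 rose and 7 fell (5 and 8 adjusted over the list alone), with a rise in the IgG receptor FCGR3A (1.34 ± 0.09) and falls in PTAFR (−0.54 ± 0.06) and TREM1 (−0.44 ± 0.05). Of 20 genes of the prostaglandin and steroid list, 4 rose and 8 fell (5 and 8 adjusted over the list alone): the prostaglandin synthesis genes PTGS2 (−1.61 ± 0.05) and PTGES (−0.77 ± 0.05) and the angiogenic factor VEGFA (−0.80 ± 0.04) fell, and HSD11B2, which inactivates cortisol, rose 2.82-fold (SE 0.11 on the log2 scale). Of 19 stress genes, 8 rose and 1 fell, with rises in GCLM (2.34 ± 0.14), HMOX1 (2.18 ± 0.17) and XBP1 (1.23 ± 0.04).

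Genes of the cell marker lists and reference genes changed with IFNT in granulocytes as well. Of all probes tested in granulocytes, 44.6% passed the threshold, so a count of changed members does not by itself set a list apart. Of 11 monocyte and macrophage markers, 5 rose and 3 fell, with rises in CD14 (1.03 ± 0.07) and C1QB (0.47 ± 0.05; not past the threshold with all 14 arrays in 1 fit) and a fall in CD36 (−1.40 ± 0.16). The eosinophil markers CCR3 (−1.34 ± 0.07) and ALOX15 (−0.21 ± 0.06) fell, 2 of 3 measured (1 rose and 2 fell adjusted over the list alone). NKG7 (0.93 ± 0.18) was 1 of 2 rises among 17 T and NK cell markers (1 adjusted over the list alone), and JCHAIN (0.35 ± 0.05) rose of 6 B cell markers. EPB42 (−0.96 ± 0.08) was 1 of 2 falls among 5 platelet and erythroid markers. MUC1 (2.84 ± 0.16) was the largest of 3 rises, with 1 fall, among 11 epithelial markers. CNN1 rose from background to at least 1.69-fold higher, of 6 endothelial and smooth muscle markers, and COL1A1 (1.42 ± 0.09) rose of 12 stromal genes. Of 12 reference genes, 1 rose and 5 fell, YWHAZ (−0.47 ± 0.07) and GAPDH (−0.30 ± 0.05) among them. All 102 GAPDH probes fell in granulocytes, by log2 changes from −0.20 to −0.47, and did so under every scaling tried.

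In all, 4633 of 10379 probes tested in granulocytes passed the threshold (1785 up and 2848 down; 5348 at an unadjusted p under 0.05). Most of these changes were small, with a median size of 0.38 on the log2 scale. Of the 4633 probes, 402 rose and 100 fell at least 2-fold. Among genes with a symbol, each counted by 1 probe, 2241 of 5036 passed. Probes without a symbol are left out of that gene count. In 4526 probes (43.6%; chance gives 2.86%) the IFNT and PBS arrays did not overlap, 4267 of the changed probes among them. Array row and treatment coincided on this slide, so a fit with row as a covariate was not possible. The design cannot tell row and treatment apart for any of these probes.

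**Figure D2:**
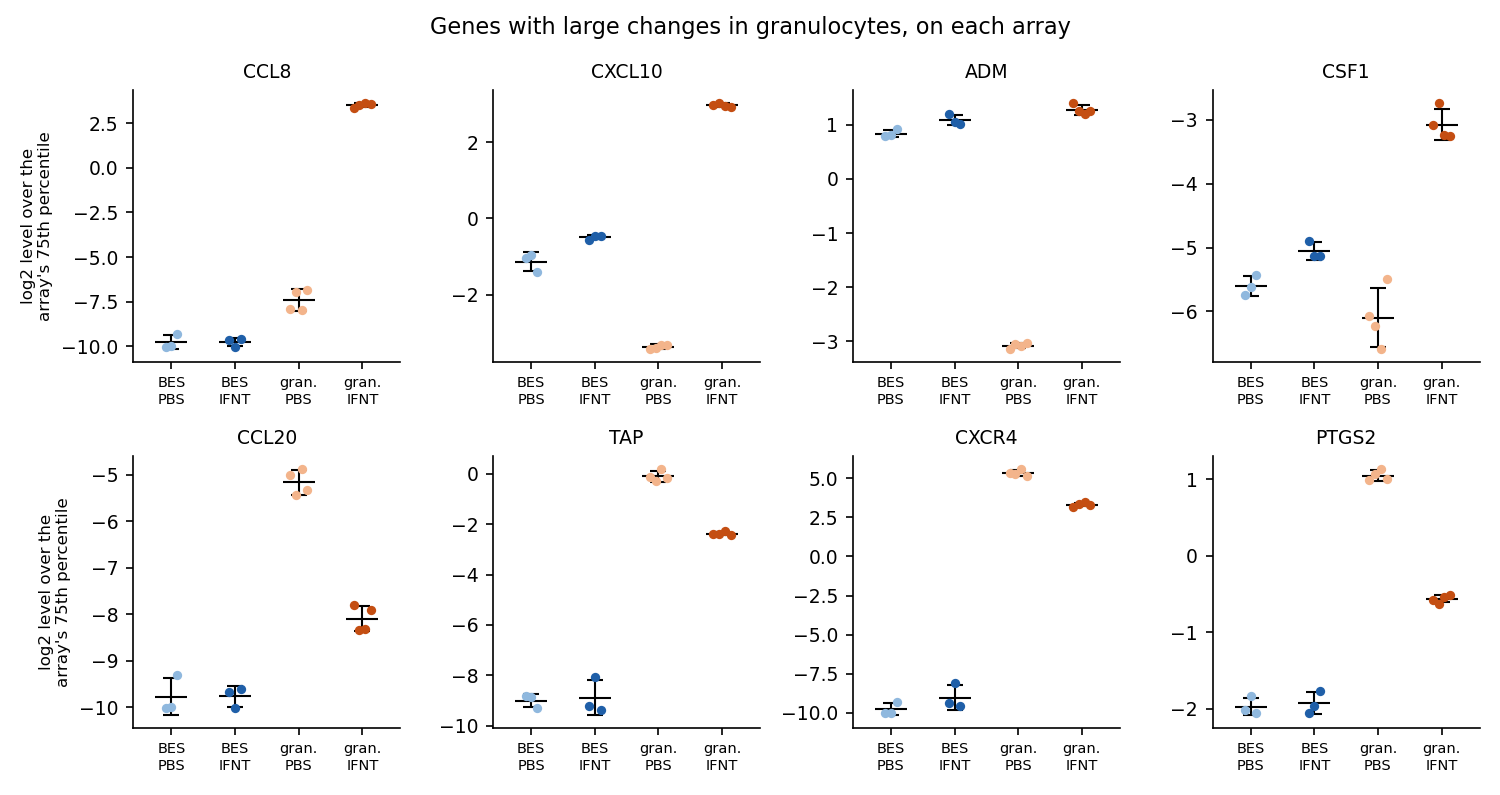
Level of 8 genes with large changes in granulocytes on each array, as log2 over the 75th percentile of that array. Points are samples (3 per BES group, 4 per granulocyte group), and bars are the mean and SD. CXCL10 rose by 6.31 and ADM by 4.36 in granulocytes, while CXCR4 changed by −2.02 and PTGS2 by −1.61.

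**Figure D3:**
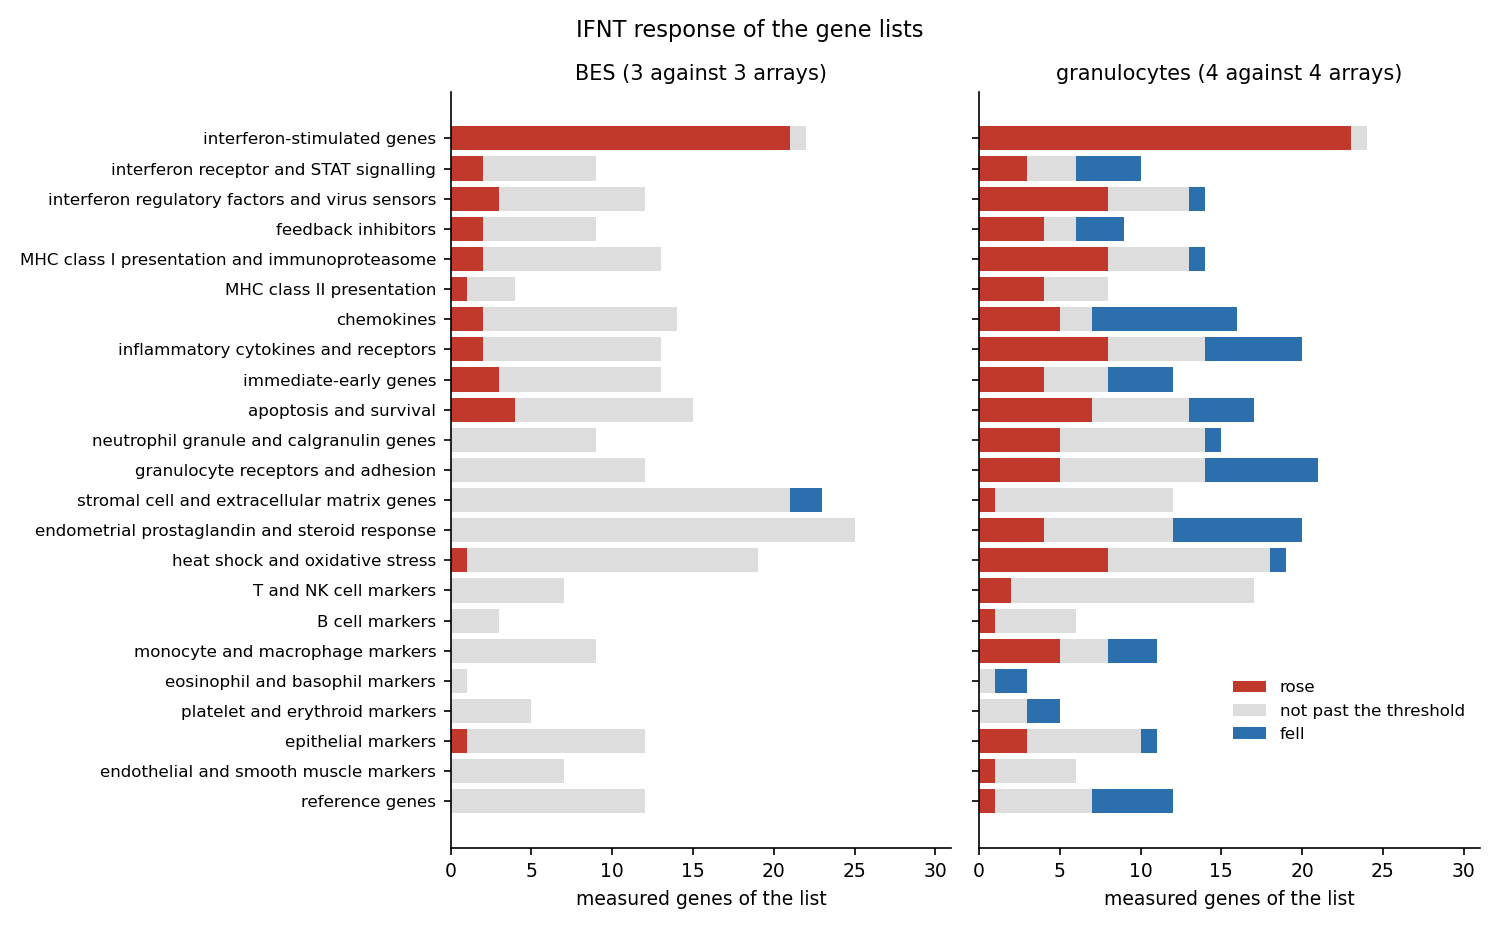
Measured genes of each of the 23 lists that rose, fell or did not pass an adjusted p of 0.05 with IFNT, in BES (left) and in granulocytes (right). Bar length is the number of genes. Of the interferon-stimulated genes, 21 of 22 rose in BES and 23 of 24 in granulocytes, while 5 of 16 chemokines rose and 9 fell in granulocytes.

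Both cell types raised a common set of genes. Of 4695 genes tested in both, 116 rose in BES and 828 in granulocytes, and 89 rose in both, against 20.5 if the lists were independent (odds ratio 17.1, Fisher's exact test, adjusted p 1.0e-44). These were 76.7% of the genes that rose in BES. The falls showed no detectable overlap beyond that of independent lists: 21 genes fell in both against 17.2 (adjusted p 0.319). Another 9 rose in BES and fell in granulocytes, against 31.1 (adjusted p 6.8e-07), and 5 fell in BES and rose in granulocytes, against 11.3 (adjusted p 0.0606). Across genes the log2 changes correlated at r = 0.417 (rho = 0.144), and at r = 0.323 without the interferon-stimulated list; genes are not independent replicates.

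**Figure D4:**
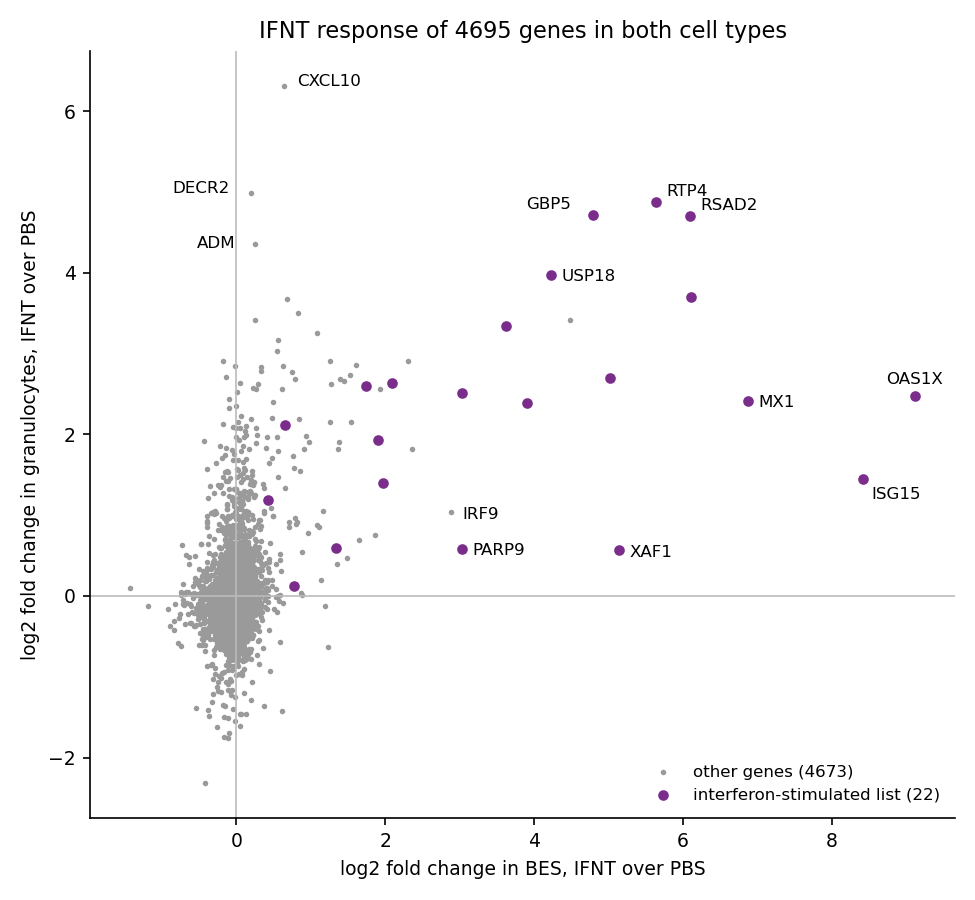
Log2 fold change with IFNT in BES (horizontal) and in granulocytes (vertical) for the 4695 genes tested in both. Each point is a gene, and the larger points are interferon-stimulated genes. RTP4 and RSAD2 lie high on both axes, ISG15 is saturated in granulocytes, MX1 and OAS1X rose more in BES, and CXCL10, DECR2 and ADM rose more in granulocytes.

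The direct contrast asked which genes responded differently in the cell types. The response was smaller in granulocytes for XAF1 by a log2 difference of −4.58 ± 0.15, for MX1 by −4.47 ± 0.10 and for PARP9 by −2.45 ± 0.06, and for OAS1X, not well above background in BES with PBS, it was at least 20.5-fold smaller. For ISG15 the fitted difference of −6.97 ± 0.13 is the lowest value that its saturated spots allow, and the values set no upper limit. Its starting levels differed: ISG15 stood at −4.03 ± 0.19 (SD, n = 3) in BES with PBS and 4.39 ± 0.08 with IFNT, and at 7.60 ± 0.12 (SD, n = 4) and 9.05 ± 0.06 in granulocytes. Differences in favour of granulocytes were 5.67 ± 0.13 for CXCL10, 4.79 ± 0.08 for DECR2 and 4.11 ± 0.09 for ADM, and PRM1 differed at least 2.29-fold. BNBD-9-LIKE, well above background on 1 array of each BES group, gave −2.56 ± 0.15. CCL8, SORD, BCL2L14, TMPRSS2, CCL20 and CXCR4 were also among the largest fitted differences, but they were not well above background in BES with PBS and in at least 1 other group, so neither the size nor the direction of their difference is measured.

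Of 24 interferon-stimulated genes, the response passed as larger in granulocytes for 5 and as smaller for 13, of which 4 and 10 were measured in all groups and 2 of the smaller ones rest on a bound (camera adjusted p 1.4e-04; adjusted p = 0.357 with an estimated correlation); with normexp background correction the counts were 9 and 10. The camera test takes in the fitted values of ISG15 and OAS1Z, whose directions are not bounded. MX2 was among those with the larger response in granulocytes (1.47). Of 14 interferon regulatory factors and virus sensors, 6 passed as responding more in granulocytes and 1 as responding less, of which 5 and 1 were measured in all groups (camera adjusted p 0.0474; adjusted p = 0.357 with an estimated correlation), IRF3 (1.95 ± 0.15) and TLR4 (1.77 ± 0.13) among the former. In all, 3197 of 12046 probes differed in response, 1411 higher and 1786 lower in granulocytes; by fitted value 407 and 137 of them reached 2-fold, of which 300 and 95 were measured in all 4 groups and 74 and 32 have no bounded direction. Of the 3197, 2979 were measured in all 4 groups, which asks only for any array well above background in each and not all saturated. Another 54 have a bound of the same direction. For 164 the direction is not bounded, because a group had no array well above background or was saturated on every array. Each treatment contrast lies within 1 slide, so a constant slide effect cancels, while the row order of the granulocyte slide does not.

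Under PBS, the cell types differed in their marker genes. Granulocytes had higher levels of all 15 neutrophil granule and calgranulin genes (median log2 difference 7.60), such as S100A12 (11.87 ± 0.09), S100A8 (14.42 ± 0.28), MMP9 (7.41 ± 0.07) and ANXA1 (2.93 ± 0.05), and of 20 of 21 granulocyte receptors and adhesion genes (median 8.56), such as ITGB2 (6.52 ± 0.07), NCF1 (5.55 ± 0.07) and CYBA (4.19 ± 0.09). BES had higher levels of 20 of 23 stromal and matrix genes (median −6.04). By the naming rule, which took the members with the highest mean level over both cell types, S100A4 (2.83-fold) and TIMP1 (−0.97 ± 0.07) were lower in granulocytes and TIMP2 (0.95 ± 0.05) and VIM (0.14 ± 0.05) higher, the last 2 with a direction that turned under another scaling. The smooth muscle genes ACTA2 (−7.65 ± 0.18) and MYLK (−5.25 ± 0.08) were lower in granulocytes, and CNN1 was at background there, at least 1995-fold lower. The epithelial gene KRT19 was also lower in granulocytes (−5.00 ± 0.16); of 13 epithelial markers 5 were higher and 8 lower, a balance that turned with normexp background correction (6 and 6, median 0.19 in place of −1.13).

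All 24 interferon-stimulated genes were higher in granulocytes than in BES before any IFNT, with a median difference of 5.78 (camera adjusted p 1.6e-07; adjusted p = 0.0695 with an estimated correlation). The granulocyte samples also held markers listed for other leukocytes. For monocytes they were CD68 (10.36 ± 0.09) and CD14 (6.77 ± 0.09), with 9 of 12 markers higher and 3 lower. Whether granulocytes express these markers themselves was not tested. GNLY (6.69 ± 0.09) of NK cells was higher, with 15 of 16 T and NK cell markers higher and 1 lower. BLK of B cells was at least 1515-fold higher, with all 6 markers higher. Of eosinophils, which are granulocytes, all 3 markers were higher, ALOX15 (10.37 ± 0.06) and CCR3 (at least 214-fold higher) among them. Platelet and erythroid markers were higher for 5 of 6, with ITGA2B at 6.57 ± 0.07, and 6 of 8 endothelial and smooth muscle markers were lower. Of the 23 lists, that of granulocyte receptors alone had an adjusted p under the threshold with an estimated correlation (adjusted p = 0.0499 with an estimated correlation).

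In all, 10784 of 11805 probes differed under PBS (5511 higher and 5273 lower in granulocytes, 10808 at an unadjusted p under 0.05), with a median log2 difference over all probes of 0.03. That median moved to −0.12 with scaling by the array median, −0.21 with quantile normalization and 0.46 with normexp background correction, so differences of that size depend on the scaling. Slide and cell type cannot be told apart in this comparison.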

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

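The tests of monocyte markers and the count of neighbouring gene pairs were chosen only after the results they concern had been seen, as was the repeat of that count with surely named probes, whose own result was not known then; the other tests were set before.

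Among genes with a test of the difference itself (limma, all 14 arrays), 86 of the 102 named genes passed the threshold for a different response in the cell types, against 26.5% of all probes tested; the naming rule took large changes and large differences, so a higher share is built in. Of the 86, 66 were measured in all 4 groups, 32 with a higher value in granulocytes and 34 with a lower one, 4 have a bound of the same direction, and for 16 the values bound no direction. Each value is the granulocyte log2 change minus the BES log2 change. Among interferon-pathway genes they were −4.58 for XAF1, −4.47 for MX1, −2.45 for PARP9, −2.32 for IFIT3, −1.86 for IRF9, −1.52 for RIGI, −1.40 for RSAD2, −0.77 for RTP4, −0.63 for IFNGR1, −0.63 for IFNAR2 and −0.56 for TLR3, against 0.52 for IRF1, 0.56 for IFIT5, 1.47 for MX2, 1.77 for TLR4 and 1.95 for IRF3. The feedback inhibitors gave −1.37 for DUSP6, 1.32 for SOCS2 and 1.58 for CISH. For the list of interferon-stimulated genes, with 5 members higher and 13 lower in granulocytes (9 and 10 with normexp background correction), the camera adjusted p was 1.44e-04 (adjusted p = 0.357 with an estimated correlation), and for that of interferon regulatory factors and virus sensors 0.0474 (adjusted p = 0.357 with an estimated correlation). Both tests take in fitted values that bound no direction, those of ISG15 and OAS1Z in the first and of 1 member in the second.

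Among chemokines and cytokines the differences were 5.67 for CXCL10, 2.48 for CSF1 and 1.23 for CCL2, against −1.36 for CCL24, −1.04 for IL10 and −1.02 for GRO1. Among antimicrobial and granulocyte genes they were −2.56 for BNBD-9-LIKE, −1.90 for DEFB13, −1.65 for MEFV and −0.50 for MMP9, against 1.17 for LTF and 1.33 for CATHL6. Immediate-early and cell death genes gave −1.02 for ATF3, −0.94 for ZFP36, −0.74 for FOS, 0.58 for IER2, −0.96 for CASP8 and −0.65 for BIRC3. Presentation genes gave −0.44 for B2M, 0.35 for CTSS, 0.46 for PSME1, 0.52 for PSMB9 and 0.68 for PSME2. Prostaglandin, steroid and stress genes gave −1.65 for PTGS2, −0.87 for VEGFA, −0.87 for PTGES, 0.29 for DNAJA1, 1.18 for XBP1, 1.45 for HSD11B2, 1.99 for HMOX1 and 2.35 for GCLM.

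Genes of the cell marker lists and reference genes gave −1.35 for CD36, −1.002 for EPB42, −0.37 for YWHAZ, −0.33 for ALOX15, −0.25 for GAPDH, 0.35 for JCHAIN, 0.47 for THY1, 1.05 for CD14, 1.56 for COL1A1 and 2.50 for MUC1. Other genes gave −1.58 for PCOLCE, 0.73 for GADD45G, 0.75 for PDE2A, 3.00 for NCOA7, 4.11 for ADM and 4.79 for DECR2.

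Some of these calls depended on the processing. DNAJA1 reversed with quantile normalization (−0.010) and lost its call without BES IFNT sample 2. PSME2, IFIT5 and PSMB9 did not pass with quantile normalization, nor CD36, ALOX15, RSAD2, RTP4 and PDE2A with normexp background correction; IRF1, PSMB9, PDE2A and TLR3 lost their calls without at least 1 of the samples.

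For genes not well above background in 1 or more groups, the fitted difference depends on substitute values. The direction is bounded for OAS1X (fitted −6.66, at least 20.5-fold), GBP4 (−2.40, at least 2.11-fold, but 0.67 with normexp background correction), CNN1 (1.65, at least 1.91-fold) and PRM1 (3.81, at least 2.29-fold). Neither size nor direction is measured where the fit gave 10.94 for CCL8, 5.40 for SORD, 4.57 for BCL2L14, 3.65 for TMPRSS2, 1.82 for OAS1Z, 1.71 for IFNB1, 1.34 for FCGR3A, 1.33 for CATHL2, 1.31 for CASP1, −1.07 for KIF5C, −1.34 for CCR3, −1.45 for LAP, −2.39 for TAP, −2.76 for CXCR4 and −2.93 for CCL20. For ISG15, saturated on all granulocyte IFNT arrays, the fitted −6.97 is the lowest value allowed, with no upper limit.

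In 7 of 210 tests of these genes and of array measures within a granulocyte group, 1 sample stood apart from the other 3, and about 1 group in 20 would do so by chance. The gap as a share of the range was 0.845 for KIF5C in PBS sample 2 (low), 0.844 for BNBD-9-LIKE and 0.843 for TAP in IFNT sample 3 (high), 0.836 for BOLA-DMB and 0.843 for IFNB1 in IFNT sample 4 (high), and 0.864 for TREM1 and 0.858 for GAPDH in IFNT sample 2 (high). In TREM1 that sample stood at a level of 3.32 and the others at 3.18 to 3.20. KIF5C was not well above background on any granulocyte PBS array, so its gap lies among values at background.

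The first pattern is the larger number of changed probes in granulocytes (4633) than in BES (414). More arrays in the granulocyte fit cannot be the whole cause, since the lowest count over 16 granulocyte fits of 3 against 3 arrays was 3411 probes, and an intensity-dependent shift between arrays cannot either, since 4680 probes passed after quantile normalization. The effect of array row on the slide stays open: across 3891 probes, the difference between rows among BES PBS samples followed the granulocyte change with a slope of 0.0109 ± 0.0053 (SE), but 1 of the rows held 1 such array, and the granulocyte rows coincide with treatment. A difference between the cell types themselves, which the design names, is untested beside it. The median absolute log2 change over all probes was 0.197 in granulocytes and 0.0983 in BES, at like standard errors (medians 0.072 and 0.063).

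The second pattern is the rise of CCL8 and CXCL10 in granulocytes, chemokines that monocytes can also make. A larger share of monocytes in the IFNT tubes would by itself raise the monocyte and macrophage markers of the fixed list together. Of these markers, 3 fell past the threshold while 5 rose, so a larger share alone does not account for their changes. The markers cannot decide whether it contributed, since 44.6% of all probes tested changed in granulocytes and IFNT may have changed the markers themselves. Monocytes carried in the granulocyte preparation and responding to IFNT may have contributed and cannot be told apart from a response of granulocytes: 11 of the markers were well above background on every granulocyte PBS array, CD14 and CD68 among them. The labels name no sort or gate that would remove monocytes, and granulocytes may express some of these markers themselves, which was not tested.

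The third pattern is that some genes next to an induced gene rose too in granulocytes. Adjacent here means next in order among protein-coding genes with a symbol, so other genes may lie between. Genes counted as of different families when the opening letters of their symbols differed. Among 1462 adjacent pairs of genes of different families, 9 had both genes raised at least 2-fold, against a mean of 2.92 in 10000 random placements of the 223 raised genes (permutation p 0.0027, one-sided); in BES, with 45 raised genes, 0 of 1679 pairs did, against 0.115. The pairs, named after their values were seen, include those that prompted the count, such as MX1 with TMPRSS2, so that p partly restates the observation. Neighbouring genes rising together and probes named for the wrong neighbour both stay open as explanations: with both probes named through an accession or gene number, 1 pair remained, ADM with SBF2, against a mean of 1.16 (permutation p 0.685).

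Other splits of the same arrays into groups of the same sizes were fitted in the same way. In granulocytes, 1 of 35 splits, the real one, gave as many probes (4633) and as many raised interferon-stimulated genes (23). The highest of the others gave 0 for both. For the levels under PBS, 1 of 35 splits gave as many probes (10784 against 4 for the next). Both shares lie under 0.05, so an arbitrary grouping of these samples is unlikely to give such counts. Splits that mix the real groups hold the difference between them in their spread, which lowers their counts. The splits cannot separate treatment from array row, or cell type from slide, and do not reach beyond these samples. For genes raised in both cell types the real split gave 89 and the highest of the other drawn splits 0; that count rests on the BES calls, for which the possible splits are too few for a share under 0.05. In the contrast of responses, 1 of 100 drawn splits gave as many probes (3197), and the next gave 2826; it was 1 of 2 drawn splits that kept the granulocyte arrays in their real groups, while splits that regrouped the granulocyte arrays gave at most 328. In BES the 10 possible splits are too few for a share under 0.05; the real one gave 414 probes and 21 raised interferon-stimulated genes, and the highest of the others 0 and 0.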

How the results depend on the processing

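No alternative was added after the data had been seen. The number of changed probes in BES, 414, was 189 with no filter on dim probes, where more probes are tested. It was 1011 with an intensity trend and robust prior and 87 with a minimum of 2-fold. With array row as a covariate it was 149, in a contrast of the IFNT samples with PBS sample 3 alone, the only PBS sample in array row 2. With 1 sample left out, where fewer samples enter, it was 183 to 534. The highest of these counts, 534, came without PBS sample 3, when array row and treatment coincide in BES as well. Whether row raised that count, and why the prior raised its own, was not tested. Under the other alternatives the number stayed within 1.5 times, from 318 to 616. Apart from the minimum of 2-fold, rises in BES (259) ranged from 129 to 432 and falls (155) from 20 to 579. The counts in granulocytes (4633) and in the contrast of responses (3197) moved beyond 1.5 times under the minimum of 2-fold alone, to 502 and 544 by that alternative's construction, and ranged from 4043 to 4669 and from 2694 to 3333 with 1 sample left out. The count under PBS (10784) stayed between 8270 and 13445, raised interferon-stimulated genes between 16 and 22 in BES and between 22 and 23 in granulocytes, and genes raised in both between 64 and 100. Of the values of named genes under the alternatives, 658 of 821 in BES kept direction and side of the threshold, 162 lost the call and 1 gained it; 1773 of 1795 did so in granulocytes, 2366 of 2443 in the contrast of responses, where DNAJA1 reversed with quantile normalization (−0.010) and GBP4 with normexp background correction (0.67), and 608 of 619 under PBS, where 3 reversed: TIMP2 with quantile normalization (−0.15) and VIM with quantile normalization (−0.87) and with the array median (−0.014), and the cause of these reversals was not tested. Between PBS and IFNT samples with the same replicate number, deviations from the group means correlated across probes at 0.047, 0.059 and −0.013 in BES and 0.145, 0.185, 0.203 and −0.118 in granulocytes. Samples with different numbers gave −0.12 to 0.09 in BES and −0.43 to 0.32 in granulocytes, ranges that take in those values. Pairing by number is thus neither shown nor refuted. On the granulocyte slide the number was also the array column. With a block for the replicate number, 318 probes in BES, 4674 in granulocytes and 3147 in the contrast passed. Raised interferon-stimulated genes then numbered 21 and 22, and genes raised in both 73. Array row could not be fitted in granulocytes. Signal over background limits the folds of genes such as CCL8, OAS1X and GBP4 to lower bounds, and saturation that of ISG15 in granulocytes; for 164 of the 3197 probes in the contrast of responses it leaves the direction open.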

Other observations

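Before any IFNT, granulocytes carried higher levels of the genes that sense and relay interferon. All 10 measured genes of interferon receptor and STAT signalling were higher than in BES (median log2 difference 5.25), as were 13 of 14 interferon regulatory factors and virus sensors (median 5.57, 1 lower) and 7 of 9 feedback inhibitors (median 4.12, 1 lower). All 8 genes of MHC class II presentation (median 7.90), 11 of 14 of MHC class I presentation (median 2.15, 3 lower), 12 of 15 chemokines (median 4.61, 2 lower) and 15 of 19 inflammatory cytokines and receptors (median 5.55, 3 lower) were higher too, with 11 of 14 immediate-early genes (median 3.37, 2 lower) and 13 of 17 genes of apoptosis and survival (median 3.49, 4 lower). Their camera adjusted p ranged from 4.7e-04 to 0.0319, and from 0.0817 to 0.246 with an estimated correlation. Of 30 prostaglandin and steroid genes, 12 were higher and 18 lower, a balance that turned with normexp background correction (15 and 13), and of 19 stress genes 10 were higher and 8 lower, which turned with quantile normalization (9 and 10). Of 12 reference genes, 4 were higher and 6 lower. Slide and cell type cannot be told apart in these values.

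The array holds 102 GAPDH probes, which read 1 gene repeatedly on the same arrays and are not independent replicates. They share any bias of an array. In granulocytes array row and treatment coincide, so a small shift there cannot be told apart from an effect of row. In BES none passed the threshold in limma (27 at an unadjusted p under 0.05; log2 changes from −0.18 to 0.08), while all 102 fell in granulocytes with a median of −0.39, and 95 of them differed between the responses. The median was −0.33 to −0.41 in granulocytes under the other scalings.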
